A study of Homo sapiens with 4 samples.

How the data were processed

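HCT116 is an established human colorectal carcinoma cell line. The series holds 4 libraries, 1 each for TAF3 (a subunit of the general transcription factor TFIID), H3K4me3 (trimethylation of histone H3 at lysine 4, a mark found at promoters), RNAPII (RNA polymerase II) and input DNA. Per the labels' protocols, monolayers were crosslinked for 10 min in 1% formaldehyde, the reaction was stopped with 125 mM glycine and chromatin was sonicated, and gel-selected fragments of about 200 bp were amplified for 15 cycles and read for 36 bp on a Genome Analyzer IIx. The TAF3 antiserum was raised against residues 290 to 389 of the human protein, per the labels. Groups were taken from the sample titles.

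Per the submitters' processing notes, the tools were CASAVA 1.8.2 and MACS 1.4.2 and the genome build was hg19. The aligner settings are not given in the sources used here. Per the file headers, peaks were called separately for each antibody against the same input library, with a tag size of 35 bp, a band width of 300 bp, a p cutoff of 1e-05, an effective genome size of 2.7 Gb, local background windows of 1000 and 10000 bp and at most 1 tag kept per position. The file headers give 20290520 tags for TAF3 (17411155 after duplicate removal), 20995096 for H3K4me3 (12560129), 20074412 for RNAPII (16841238) and 19690799 for input (19185386). The share of redundant tags was 14.2% for TAF3, 40.2% for H3K4me3, 16.1% for RNAPII and 2.57% for input. With 1 tag kept per position, the count that a densely covered place can reach is bounded.

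Each antibody has a full and a filtered peak list. In the full lists the deposited tag count per peak is a whole number that is not scaled to depth, the deposited fold enrichment is a ratio of tags at the summit to the local background MACS expected, the deposited score is the negative log10 of the MACS p-value multiplied by 10, and the deposited false discovery rate is a percent that MACS estimated by swapping antibody and input. All of these per-peak values are the authors' own. The filtered lists were checked against the full lists and hold exactly the peaks with a fold enrichment above 5 and a false discovery rate below 5%. The score reads 3100 for peaks whose p was too small to be written, and a few peaks carry scores above it, so scores were treated as tied from 3100 upward and ties were ordered by fold enrichment.

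The filtered lists were compared here by overlap of at least 1 bp, with Wilson 95% intervals on the share of peaks. These intervals cover the counting of peaks only. There are no replicates, peaks are not replicates, no p-value is given across peaks, and no leave-one-out could be made. Each overlap was set beside 1000 random circular shifts of a list along each chromosome, and beside local shifts of 10 to 100 kb. Differences between shares carry Newcombe intervals. H3K4me3 and RNAPII peaks were split into 5 equal groups (quintiles) by fold enrichment. Each TAF3 peak with both partners was paired with its overlapping H3K4me3 and RNAPII peaks of highest fold enrichment for 3 rank correlations across peaks. All 3 fold enrichments are relative to the same input, so the correlation that input counting noise alone gives was simulated 100 times. In a further simulation of 2700000 windows of 1000 bp in which no library was enriched, 0 windows passed the filter. At its mean of 7.106 input tags per kb this outcome was all but fixed in advance. It does not measure how many deposited peaks are false.

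The main comparisons, their alternatives and the rule for named peaks were fixed before the data were examined, apart from the alternatives and tests of explanations that the closing section identifies as chosen later. The plan did not list the correlations across TAF3 peaks, the TAF3 share along the RNAPII list or the order of summits. Nor did it list the comparison with and without RNAPII in the lowest decile. The rule names the 5 peaks of highest fold enrichment in each list and overlap class, with ties ordered by tags and then coordinate. Up to 5 of these are given below, from the top of the order, and for some lists and classes none. Regions are named by hg19 coordinates, counted from 1. The gene annotation at hand was on another build, so genomic location, promoter classes, the 13 gene lists and promoter sequence are not analysed here, and no gene is named. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The overlap code was tested on simulated data, where 9 of 9 checks passed, and its counts equalled those of bedtools 2.31.1 for 6 of 6 list pairs.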

Results

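The series title names the interaction of H3K4me3 with TAF3 and the assembly of the preinitiation complex, and the libraries map where TAF3, H3K4me3 and RNAPII lie along the genome of HCT116 cells. The question for each comparison was how far the peaks of these 3 antibodies fall at the same places. After duplicate removal 17411155 tags remained for TAF3, 12560129 for H3K4me3, 16841238 for RNAPII and 19185386 for input.

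TAF3 gave the shortest list, H3K4me3 the strongest peaks and RNAPII the longest list. There were 11765 TAF3 peaks covering 19.6 Mb, 14298 H3K4me3 peaks covering 33.0 Mb and 25013 RNAPII peaks covering 54.6 Mb. The median peak was 1549 bp wide for TAF3, 2240 bp for H3K4me3 and 1623 bp for RNAPII, with 187, 679 and 223 tags respectively. The median fold enrichment over input was 36.1 for TAF3, 126.1 for H3K4me3 and 44.8 for RNAPII. Peaks held 15.0% of the TAF3 tags, 81.3% of the H3K4me3 tags and 51.6% of the RNAPII tags. The widest RNAPII peak spanned 43722 bp, compared with 8492 bp for TAF3 and 12312 bp for H3K4me3.

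Nearly every TAF3 peak lay in H3K4me3-marked chromatin. Of 11765 TAF3 peaks, 11527 overlapped an H3K4me3 peak (98.0%, 95% interval 97.7 to 98.2%), compared with a mean of 2.32% after random shifts and 5.74% after local shifts. H3K4me3 peaks covered 96.8% of the bases in TAF3 peaks, and 83.8% of the 11527 TAF3 peaks lay wholly inside their H3K4me3 peak, which had a median width 1.53 times that of the TAF3 peak. The 5 TAF3 peaks of highest fold enrichment were at chr10:70090897-70093181 (224-fold, 1067 tags), chr5:60626202-60629880 (215-fold, 621 tags), chr10:74451479-74453105 (195-fold, 511 tags), chr19:2268865-2271787 (186-fold, 701 tags) and chr2:8821907-8824057 (178-fold, 485 tags). All 5 overlapped both an H3K4me3 and an RNAPII peak.

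TAF3 peaks also coincided with RNAPII peaks. RNAPII peaks overlapped 11704 of the 11765 TAF3 peaks (99.5%, 95% interval 99.3 to 99.6%), against 3.93% after random shifts and 11.4% after local shifts. Both partners were present at 11484 TAF3 peaks (97.6%, 95% interval 97.3 to 97.9%). With single shares this high, that share could hardly differ from their product of 97.47%, so its nearness does not show independence. Neither partner was present at 0.15% of TAF3 peaks, against 0.010% from the product of the shares without each partner. The peaks with both partners had a median TAF3 fold enrichment of 36.7. With the full lists, which include peaks under the authors' filter, the share with both partners was 86.0%. The RNAPII list is the longer, and with 11765 peaks per list the order turned, to 89.4% of TAF3 peaks on RNAPII and 92.8% on H3K4me3.

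**Figure D1:**
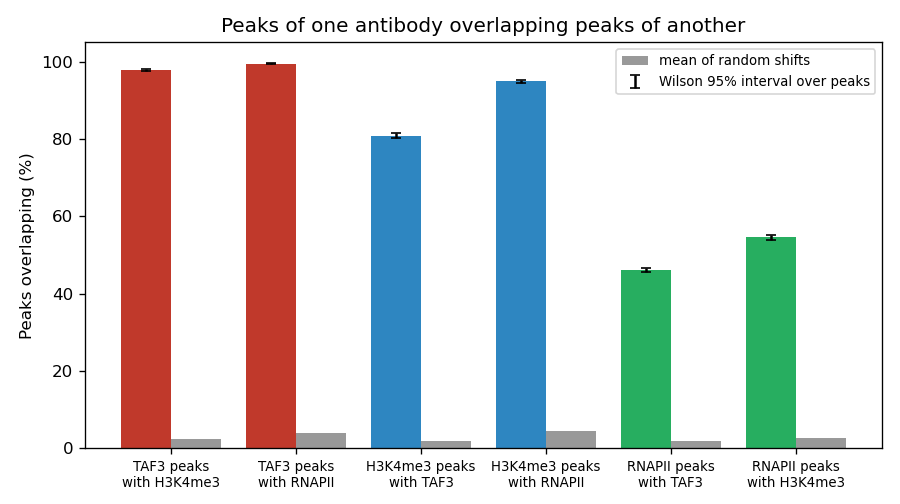
Share of peaks of each antibody, in percent, that overlapped a peak of another antibody, with Wilson 95% intervals over peaks and, in grey, the mean of 1000 random shifts. TAF3 peaks overlapped the other lists at 98.0% and 99.5%, RNAPII peaks at 46.2% and 54.6%.

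TAF3 peaks that lacked a partner were few and had lower fold enrichment. There were 220 TAF3 peaks with RNAPII and no H3K4me3 peak, with a median fold enrichment of 16.8, and 131 of them overlapped an H3K4me3 peak of the full list. The strongest were at chr7:25894620-25895189 (49.1-fold, 47 tags), chr12:6999686-7001032 (48.5-fold, 116 tags) and chr10:5488363-5488893 (45.1-fold, 60 tags), followed by chr19:36421921-36422904 (41.7-fold, 135 tags) and chr16:69563472-69564229 (39.2-fold, 84 tags). Another 43 TAF3 peaks had H3K4me3 and no RNAPII peak in the filtered lists (median 25.9-fold), led by chr3:128444634-128445983 (66.6-fold) and chr12:49245271-49247415 (64.4-fold). Of these 43, 42 overlapped an RNAPII peak of the full list, and 35 overlapped a left-out RNAPII peak with a score at or above 3100. The region on chromosome 3 is an example, where an RNAPII peak of 171-fold enrichment and 291 tags at 128444667-128445914 carried a false discovery rate of 18.2%. The remaining 18 TAF3 peaks had neither partner in the filtered lists (median 12.2-fold). They were led by chr19:55690147-55690846 (29.6-fold, 65 tags), which overlapped an H3K4me3 peak of 12.7-fold in the full list. In the full lists 5 of the 18 overlapped an H3K4me3 peak and 4 an RNAPII peak.

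**Figure D2:**
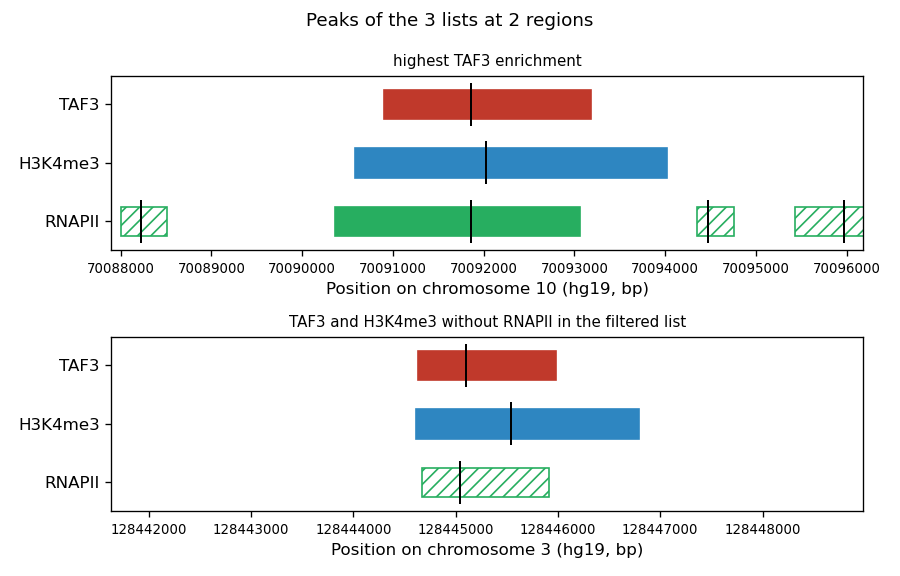
Peaks of the 3 lists along hg19 positions in bp on chromosome 10 and chromosome 3, where filled bars are filtered peaks, hatched bars are peaks outside the authors' filter, and black lines are summits. On chromosome 10 the TAF3 and RNAPII summits were at 70091856 and 70091865, and on chromosome 3 the RNAPII peak was hatched with 171-fold enrichment.

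Most, though not all, H3K4me3 peaks overlapped a TAF3 peak, and most overlapped an RNAPII peak. TAF3 peaks overlapped 11561 of 14298 H3K4me3 peaks (80.9%, 95% interval 80.2 to 81.5%), against 1.92% after random shifts, and RNAPII peaks overlapped 13580 (94.98%, 95% interval 94.6 to 95.3%), against 4.44%. With 11765 peaks per list the order turned, to 91.9% with TAF3 and 85.3% with RNAPII. The H3K4me3 peaks with both TAF3 and RNAPII numbered 11523, with a median of 141-fold enrichment and 793 tags. The 2057 with RNAPII and no TAF3 had a median of 50.5-fold and 164 tags, and the 680 with neither had 35.8-fold and 88 tags. Some strong H3K4me3 peaks had RNAPII and no filtered TAF3 peak, led by chr9:100173473-100175636 (230-fold), chr10:64027184-64029372 (226-fold), chr1:12289685-12291704 (225-fold), chr19:708169-710164 (224-fold) and chr14:92301837-92303731 (219-fold), and all 5 overlapped a TAF3 peak of the full list, at 12.2- to 19.4-fold. Among H3K4me3 peaks with neither TAF3 nor RNAPII in the filtered lists, the strongest was chr14:73358916-73362228 (181-fold, 1026 tags), followed by chr10:52750038-52752200 (143-fold, 518 tags), chr12:85429468-85430832 (135-fold, 209 tags), chr3:18464948-18467879 (134-fold, 838 tags) and chr4:149365186-149367572 (130-fold, 533 tags). All 5 overlapped a TAF3 peak and 4 an RNAPII peak of the full lists, as did 191 and 467 of the 680 in this class.

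The share of H3K4me3 peaks with TAF3 rose with the strength of the mark. From the lowest to the highest quintile of H3K4me3 fold enrichment, TAF3 peaks were present at 34.9%, 77.9%, 94.4%, 97.9% and 99.2%. The highest quintile exceeded the lowest by 64.3 percentage points (95% interval 62.5 to 66.1). RNAPII was present at 79.7% of the lowest quintile and 99.8% of the highest. Along the RNAPII list TAF3 was present at 0.54%, 2.82%, 37.7%, 90.7% and 99.1% of peaks from the lowest to the highest quintile. The RNAPII list is longer and its lowest quintile reaches down to 5.06-fold, against 9.43-fold for H3K4me3, so the quintiles of the lists do not match in strength. These shares use the authors' cutoff for TAF3, and 94.3% of H3K4me3 peaks overlapped a TAF3 peak of the full list.

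**Figure D3:**
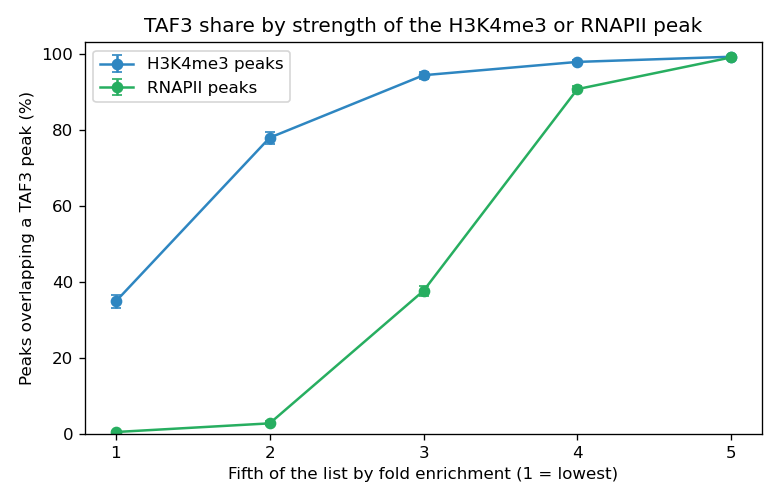
Percent of H3K4me3 and RNAPII peaks that overlapped a TAF3 peak, by quintile of fold enrichment within each list, where bars are Wilson 95% intervals over peaks. The share rose from 34.9% to 99.2% along the H3K4me3 list and from 0.54% to 99.1% along the RNAPII list.

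TAF3 was found mainly at those H3K4me3 peaks that also carried RNAPII. It was present at 84.9% of the 13580 H3K4me3 peaks with RNAPII (95% interval 84.2 to 85.5%) and at 38 of the 718 without (5.29%, 95% interval 3.88 to 7.18%), a difference of 79.6 percentage points (95% interval 77.6 to 81.1). Within the lowest quintile of H3K4me3 enrichment the shares were 43.4% of 2279 and 1.38% of 581, a difference of 42.1 points (95% interval 39.7 to 44.2). Within the lowest decile, where the median H3K4me3 enrichment was 27.6-fold with RNAPII and 27.9-fold without, TAF3 was present at 34.6% of 1049 peaks and at 1.31% of 381. The upper quintiles held few peaks without RNAPII, 14 in the fourth and 7 in the highest, and TAF3 was present at 12 and 7 of these. With the left-out RNAPII peaks of score 3100 or more added to the list, 682 H3K4me3 peaks lacked RNAPII, 4 of them had TAF3, and the difference was 84.3 points. Averaged over the quintiles of H3K4me3 enrichment, with each quintile weighted by its number of peaks without RNAPII (581 of 718 in the lowest), the difference was 46.2 points.

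RNAPII peaks divided into a class with both partners and a class of similar size with neither. Of 25013 RNAPII peaks, 11340 overlapped both TAF3 and H3K4me3 (45.3%, 95% interval 44.7 to 46.0%), 2326 overlapped H3K4me3 alone, 206 overlapped TAF3 alone and 11141 overlapped neither (44.5%, 95% interval 43.9 to 45.2%). The median RNAPII fold enrichment was 108.2 with both, 37.02 with H3K4me3 alone, 52.3 with TAF3 alone and 17.8 with neither. The strongest RNAPII peaks with both were at chr19:2474578-2477625 (313-fold), chr13:45005909-45012245 (306-fold) and chr11:69450987-69473760 (302-fold, 22774 bp wide). RNAPII peaks with neither partner were led by chr9:21499625-21534538, which spanned 34914 bp and held 11543 tags at 251-fold enrichment, followed by chr15:65587803-65589342 (218-fold), chr10:16933344-16934477 (212-fold), chr6:74221164-74227341 (202-fold) and chr6:30771864-30775824 (197-fold). Of these 5, 3 overlapped a TAF3 peak and 1 an H3K4me3 peak of the full lists, as did 2096 and 1283 of the 11141 in this class. The strongest with TAF3 and no filtered H3K4me3 peak was chr1:148240750-148242274, with 290-fold enrichment of RNAPII and 31.0-fold of TAF3. It overlapped an H3K4me3 peak of 18.6-fold in the full list. Of the 206 in this class, 124 overlapped an H3K4me3 peak of the full list.

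TAF3 summits sat on RNAPII summits and to the side of H3K4me3 summits. The median distance from a TAF3 summit was 44 bp to the nearest RNAPII summit (quartiles 16 and 178 bp) and 234 bp to the nearest H3K4me3 summit (quartiles 118 and 424 bp). RNAPII summits lay within 50 bp of 53.9% of TAF3 summits, compared with 7.39% for H3K4me3 summits. A random base of the overlapping peak lay at a median of 445 bp for RNAPII and 622 bp for H3K4me3. Of the 11484 TAF3 peaks with both partners, 11340 had TAF3, H3K4me3 and RNAPII summits at different positions. Among these 11340, the TAF3 summit lay between the other summits in 61.3%, the RNAPII summit in 30.3% and the H3K4me3 summit in 8.42%. With TAF3 and RNAPII summits so close together, an H3K4me3 summit can seldom lie between them. Equal shares are therefore not the expectation, and none was computed. At the strongest TAF3 peak, on chromosome 10, the TAF3 summit was at 70091856, the RNAPII summit at 70091865 and the H3K4me3 summit at 70092020.

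**Figure D4:**
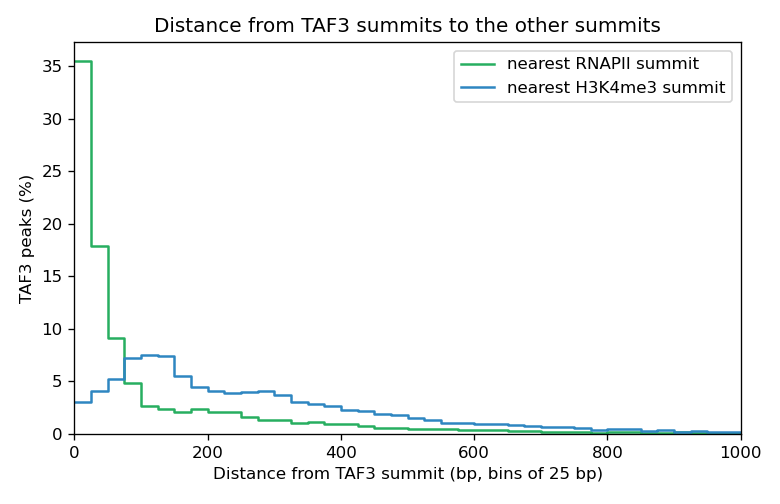
Percent of the 11765 TAF3 peaks, in bins of 25 bp, by distance in bp from the TAF3 summit to the nearest RNAPII summit and the nearest H3K4me3 summit. RNAPII distances were highest in the first bin, at 35.5%, and H3K4me3 distances between 100 and 125 bp, at 7.48%.

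Places with more TAF3 had more RNAPII and more H3K4me3. Across the 11484 TAF3 peaks with both partners, which are not independent replicates, the rank correlation of fold enrichment was 0.74 between TAF3 and RNAPII (95% resampling interval over peaks 0.73 to 0.75), 0.56 between TAF3 and H3K4me3 (0.55 to 0.57) and 0.56 between H3K4me3 and RNAPII (0.54 to 0.57). Counting noise of the shared input alone gave simulated correlations of 0.11, 0.11 and 0.14. The covariance of log2 fold enrichment was 0.36, 0.29 and 0.24, against simulated values of 0.067, 0.066 and 0.066. Given H3K4me3, the partial correlation of TAF3 with RNAPII was 0.62, and given RNAPII, that of TAF3 with H3K4me3 was 0.26. With tags per bp these partial correlations were 0.56 and 0.49. The gap between the TAF3 correlations with RNAPII and with H3K4me3 was 0.18 for fold enrichment, 0.059 for tags per bp and 0.022 for tags per peak, so its size depended on the measure. The correlation of H3K4me3 with RNAPII fell to 0.28 with tags per bp.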

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

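The test of TAF3 peaks below the filter and both tests of the RNAPII filter were chosen after the results were seen, and the comparison within the lowest quintile was set before.

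Signal in TAF3 peaks that the report's comparisons leave out stood above random shifts. TAF3 peaks outside the authors' filter numbered 6122, with a median of 28 tags and 9.84-fold enrichment. Of these, 45.3% overlapped a filtered H3K4me3 peak, against a mean of 1.77% and a maximum of 2.39% after random shifts, and 78.5% overlapped a filtered RNAPII peak, against 3.10% and 4.17%.

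H3K4me3 peaks without a TAF3 peak were mostly weaker H3K4me3 peaks. Of the 2737 such peaks, 70.2% overlapped a TAF3 peak below the filter, against 0.54% after random shifts of those peaks, so a TAF3 detection threshold may account for 1921 of them, while 816 overlapped no TAF3 peak of either list. Within the lowest quintile, TAF3 share differed by 42.1 percentage points between peaks with and without RNAPII. With 99.5% of TAF3 peaks on RNAPII peaks, a large difference was all but fixed in advance. Fold enrichment from 1 library is also an imperfect measure of strength. The split therefore cannot decide whether H3K4me3 strength is the whole account. A biological tie between TAF3 and RNAPII at weakly marked places stays open, since RNAPII peaks are subject to a threshold of their own.

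A set of 40 RNAPII peaks with scores of at least 3216 was left out of the filtered list by a false discovery rate of 5% to 20%. Their fold enrichment ran from 25.4 to 171 with a median of 81.9, and 33 exceeded 50. The 8059 RNAPII peaks with a score of exactly 3100 had a false discovery rate of at most 0.06%, and 0 TAF3 and 0 H3K4me3 peaks at or above that score were left out.

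Many of the 43 TAF3 peaks with H3K4me3 and no RNAPII peak lie where this filter removed an RNAPII peak. Of these, 35 overlapped one of the left-out strong RNAPII peaks, 7 overlapped only an RNAPII peak with a score under that of every filtered peak, and 1 overlapped none. Weak RNAPII peaks therefore do not make up the class, and removal of strong RNAPII peaks by the false discovery rate is a candidate explanation for most of it. One way this could arise is that p-values too small to be written were set to 3100, so that somewhat larger p-values ranked above them, where the estimate rests on few peaks, and this mechanism was not tested. No biological explanation was tested.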

How the results depend on the processing

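The comparisons against the other antibody's full list, with the left-out RNAPII peaks added, averaged over quintiles, with the strongest overlapping peak, and the correlations by tags per bp and per peak were chosen after seeing the data. Of 64 alternative values, 18 stayed within the 95% interval of the reported value. With full lists the shares were 86.6% for TAF3 on H3K4me3, 97.4% for TAF3 on RNAPII, 82.8% for H3K4me3 on TAF3, 93.4% for H3K4me3 on RNAPII and 86.0% for TAF3 on both. With the upper 50% of each list they were 76.9% for TAF3 on H3K4me3, 99.6% for TAF3 on RNAPII, 63.4% for H3K4me3 on TAF3 and 76.6% for TAF3 on both. With 11765 peaks per list they were, in the order used for full lists, 92.8%, 89.4%, 91.9%, 85.3% and 84.7%. So with equal list lengths TAF3 and H3K4me3 peaks each overlapped the other list more often than the RNAPII list, the opposite of the order in the filtered lists. The upper 50% drops peaks from every list, and 11765 peaks per list drops peaks from the H3K4me3 and RNAPII lists alone. Against the other antibody's full list the shares, in that order, were 99.1%, 99.9%, 94.3%, 98.5% and 99.1%. With 50% of the peak covered, TAF3 on RNAPII was 99.3%, H3K4me3 on TAF3 71.7%, H3K4me3 on RNAPII 83.1% and TAF3 on both 97.2%. With the summit inside the other peak, H3K4me3 on TAF3 was 80.1% and H3K4me3 on RNAPII 93.3%, and within 1 kb H3K4me3 on TAF3 was 81.5%. Leaving out chromosomes X and Y moved no share beyond its interval. With the left-out RNAPII peaks added, TAF3 on RNAPII was 99.8%, TAF3 on both 97.9%, the TAF3 peaks with H3K4me3 and no RNAPII fell from 43 to 8, and the TAF3 difference between H3K4me3 peaks with and without RNAPII was 84.3 points. That difference was 85.6 points with full lists, 62.0 with the upper 50% of each list and 46.2 when averaged over quintiles of H3K4me3 enrichment weighted by their peaks without RNAPII. Local shifts gave 5.74% for TAF3 on H3K4me3, 11.4% for TAF3 on RNAPII, 4.72% for H3K4me3 on TAF3 and 12.1% for H3K4me3 on RNAPII. The rise in TAF3 share from the lowest to the highest H3K4me3 group was 68.3 points ranked by tags, 67.5 by score, 60.2 by width and 73.9 in deciles. By tags per bp the correlation was 0.602 for TAF3 and RNAPII, 0.543 for TAF3 and H3K4me3 and 0.282 for H3K4me3 and RNAPII, and by tags per peak the last pairs gave 0.713 and 0.540. Summit distances to the strongest overlapping peak, at 43 bp for RNAPII and 231 bp for H3K4me3, stayed within the 95% resampling intervals of the medians, 42 to 45 and 228 to 240 bp. The cause was not tested. Alternatives for genomic location, promoter classes, gene lists and promoter sequence were not run. A peak under the cutoff at these depths is not shown to be absent. No paired analysis was possible because there is 1 library per antibody.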

Other observations

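The tests of the gap between correlations, of unequal peak arms, of counting noise and of readily precipitated regions were chosen after the results were seen, and those of the TAF3 to RNAPII correlation against the shared input and of the H3K4me3 summit position were set before.

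RNAPII peaks away from both partners lay nearer to TAF3 peaks than after random shifts along the chromosomes. The 11141 RNAPII peaks with neither TAF3 nor H3K4me3 lay at a median of 16715 bp from the nearest TAF3 peak (quartiles 6255 and 46127 bp), against 141164 bp after 20 random shifts. Within 10 kb of a TAF3 peak lay 36.1% of them, against 10.7% after those shifts. Local shifts were not run for this distance. It therefore does not separate nearness to TAF3 from both lists being dense in the same regions. Of the 1615 RNAPII peaks at least 5000 bp wide, 48.9% overlapped a TAF3 peak (95% interval 46.5 to 51.4%), close to the 46.2% of all RNAPII peaks.

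By chromosome, leaving aside Y with 1 peak, the share of H3K4me3 peaks with TAF3 ran from 76.8% on chromosome 18 (95% interval 70.6 to 82.0%) to 86.1% on chromosome 16 (83.2 to 88.6%). The 18 TAF3 peaks with neither partner had a median of 22.8 tags per kb for each unit of fold enrichment, with wide quartiles of 4.26 and 54.1. All other TAF3 peaks had a median of 3.18 (quartiles 2.53 and 4.12).

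It was hypothesised that the H3K4me3 summit lies downstream of TAF3 along the direction in which RNAPII extends. The test used 515 RNAPII peaks with a single TAF3 summit that reached at least 3000 bp on the longer side and at least 3 times as far as on the shorter side. The H3K4me3 summit lay on the extended side in 74.0% (95% interval 70.0 to 77.6%), at a median of 178 bp from TAF3 (quartiles -30 and 428 bp). A random base lay on that side in 61.1% for the H3K4me3 peaks and 84.7% for the RNAPII peaks, so the share alone does not separate the hypothesis from unequal peak arms. For the 445 summits no farther from TAF3 than the shortest arm of either peak, both sides are equally reachable. Their share on the extended side was 71.7% (95% interval 67.3 to 75.7%), against 50% if reach alone set the side. H3K4me3 peaks reached a median of 1710 bp from the TAF3 summit on the extended side and 1153 bp on the other. A summit near the middle of such a peak would also lie on the extended side. The test therefore cannot exclude unequal H3K4me3 arms as the whole cause. The direction of transcription was not annotated, so the extended side is not shown to be downstream. The RNAPII summit lay on the extended side in 43.3%, at a median of -4 bp.

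TAF3 enrichment tracked RNAPII enrichment more closely than H3K4me3 enrichment across TAF3 peaks, with a gap in correlation of 0.18 (95% interval 0.16 to 0.19). The shared input library is argued against as the cause of the TAF3 to RNAPII correlation, which was 0.602 with tags per bp, a measure without input, and as the whole cause of the gap, which was 0.059 (0.043 to 0.076) with that measure. It may account for part of the gap, which dropped by 0.12 (0.10 to 0.14), but tags per bp also replace the summit by the mean over the peak, so this stays open. The H3K4me3 partners held 1.90 times the median tags of the RNAPII partners, counted over whole peaks. Fold enrichment rests on tags at the summit, which were not compared, so this ratio cannot decide on counting noise in H3K4me3. Compression of H3K4me3 counts by duplicate removal was not tested. Regions that precipitate readily with any antibody cannot be told apart from a biological link, since no unrelated antibody was analysed here. H3K4me3 and RNAPII also correlated, at 0.559 by fold enrichment and at a lower 0.282 by tags per bp.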
